A study of Mus musculus with 6 samples.

How the data were processed

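The series measured RNA of whole mouse kidney in 6 libraries, 3 of wild type mice and 3 of mice lacking LIGHT (TNFSF14), all adult males on a C57BL/6J background after bilateral renal ischemia of 32 min and reperfusion of 24 h. Groups and replicate numbers were taken from the sample titles. The labels number the samples of a group from 1 to 3 and do not state for each that it is a different mouse, so p-values measure the spread between these samples. Total RNA was extracted with TRIzol and made into libraries with a stranded KAPA kit, per the labels' protocols. Whether the strand was used in counting is not given in the sources used here.

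The deposited values are FPKM per gene, made by the authors. FastQC, HISAT2, StringTie and the mouse build mm10 are named in the submitters' processing notes, with no versions, and the annotation is not given in the sources used here. The table of all libraries held 13026 genes under 13020 symbols, and the values of each library's own file were identical to it. In every row the higher of the group means was at least 0.50043 FPKM, so genes below about 0.5 FPKM in both groups are outside the table. FPKM hold no read counts, so the depth of each library is unknown, no count model was used, and no interval for counting error was computed. Tnfsf14 was not analysed here, and the test planned for its level was not run.

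Genes with a mean FPKM of at least 0.5 over the 6 libraries were kept, which left 12836 and removed 190. Values were put on the scale log2(FPKM + 1), and LIGHT knockout was compared with wild type in limma 3.58.1 under R 4.3.3, with empirical Bayes moderation and a mean-variance trend. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all genes kept, with a threshold of 0.05. An exact permutation test of 3 against 3 cannot give a two-sided p below 0.1, so single genes rest on the moderated test. In each gene, means and SD are of FPKM, while log2 fold changes and their SE are from the fit.

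Before the data were examined, 40 gene lists were fixed from knowledge of kidney ischemia, kidney cell types and LIGHT signalling, and 36 of them had at least 3 genes kept. The lists of T and NK cells, B and plasma cells, adrenal and skeletal muscle had 1, 2, 2 and 0 genes kept and were not tested. Each list was compared with all other genes by camera with an inter-gene correlation of 0.01, with adjustment over the lists. Beside it stood 2 further tests, camera with the correlation estimated from the residuals, and fry. Unlike camera, fry tests a list against no change and not against the other genes. The adjusted p given beside each list is from camera.

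The rule for named genes was also fixed before the data were examined. It took genes with a mean of at least 1 FPKM, an adjusted p under 0.05 and no overlap between the groups, up to 12 per direction, without predicted models. It filled the places up to 8 per direction with genes of smallest unadjusted p and a fold of at least 1.5. For each list it took up to 4 members with the smallest p in the direction of most members, up to 2 for lists without a call, and further members past the threshold in the other direction. Atf5 is such a member. The receptor genes Ltbr and Tnfrsf14 were to be given always. Lcn2, Npas2, the genes that overlap a called gene and the genes named only in the closing section are outside this rule and were chosen after their values were seen.

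Positions are from GENCODE M21, built on the same assembly as mm10, where 13005 of the 13026 identifiers were matched after removing the version. Near-identical copies were marked by the share of a gene's 31-base words that occur in transcripts of another gene, and overlaps by position. Values of such copies and of overlapping genes are uncertain, since the way reads were divided among them is not given in the sources used here.

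The fit was tested on simulated data made from the 12836 genes' own means and spreads, with 200 genes changed in each of 10 runs. For LIGHT knockout against wild type, 70.1% of genes changed 2-fold, 92.7% of those changed 4-fold and 97.3% of those changed 8-fold were called, and 5.76% of all calls were false. Changed genes were drawn from those with a mean log2(FPKM + 1) of at least 1. The 10 runs gave 1839 calls in all, against 15 in the data. More calls make the adjusted threshold easier to pass, so these shares may be too high for the data. A list shifted by 0.5 on the log2 scale was called in 10 of 10 runs by camera with the preset correlation, in 8 with the estimated correlation and in 10 by fry. Genes in that simulation were independent, which genes of 1 list in a tissue are not.

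The alternatives tried were other pseudocounts, other filters on low values, 4 other scalings, variance models without the trend, with robust moderation and with library weights, the replicate number as a block, each library left out in turn, a minimum fold, and other set tests. Others were added after the data were seen, namely leaving out genes in near-identical copies, leaving out genes near Tnfsf14 from the gene and list counts, and the estimated correlation without knockout library 3. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.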

Results

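Whole-kidney RNA was profiled in 6 mouse libraries, 3 from wild type males and 3 from males lacking LIGHT, a cytokine of the tumour necrosis factor superfamily encoded by Tnfsf14. All 6 kidneys had been through surgery in which the blood supply of both kidneys was stopped for 32 min and then restored for 24 h. No unoperated kidneys were analysed here, so the comparison is between genotypes after injury and not between injured and uninjured tissue. The deposited table gave 13026 genes in FPKM, a measure scaled for transcript length and library total, and 12836 of them were tested. FPKM summed to between 299667 and 318493 per library, and mitochondrially encoded genes held between 12.71 and 15.21% of that sum. The number of reads behind each library is unknown, because FPKM carries no depth. Knockout library 3 stood apart from the rest: its Pearson correlation with the other libraries across genes was 0.934 to 0.956, against 0.976 to 0.989 among the other 5. On the first principal component, which held 55.3% of the variance, it lay at 48.98 while the others lay between -15.65 and -0.05.

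The question of the comparison was how the loss of LIGHT changed kidney gene expression after ischemia and reperfusion. Tnfsf14 itself, at 57189492 to 57194177 on chromosome 17 (mm10), was not analysed here, so the genotype labels were not checked on the targeted gene. The transcripts of its receptors did not pass the test. Ltbr, the lymphotoxin beta receptor, averaged 52.9 ± 4.77 FPKM in wild type and 49.0 ± 9.20 in knockout (SD, n = 3 each), with a log2 fold change of -0.12 ± 0.16 (SE) and a limma adjusted p of 0.809. Tnfrsf14, which encodes the herpesvirus entry mediator, was near the lower limit of the table at 0.541 ± 0.156 FPKM in wild type and 0.839 ± 0.451 in knockout (limma adjusted p = 0.709).

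Few single genes separated the genotypes. Of the 12836 genes, 15 passed a limma adjusted p under 0.05, 3 higher and 12 lower in the knockout, and 1037 had an unadjusted p under 0.05, where 641.8 are expected by chance. Other splits of the 6 libraries into 3 and 3 gave 218 to 832 genes at that unadjusted p, so some of them also exceeded 641.8. Jchain, which encodes the joining chain of polymeric immunoglobulins, was 5.28-fold higher in the knockout. The gene for Wdfy1, an endosomal adaptor protein, was 2.88-fold higher, and that for Dbp, a transcription factor driven by the circadian clock, was 2.25-fold higher. The named genes that passed and fell were Tmem254a, Tmem254b, Tmem254c, Plac9b and Entpd4, all members of families of near-identical copies, and Nkiras2 and Cdipt. All fold changes are on the log2(FPKM + 1) scale, which understates the change of genes of low level.

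Jchain (ENSMUSG00000067149.6, chromosome 5, 88519809 to 88527891) rose from 0.651 ± 0.322 to 7.60 ± 0.550 FPKM (SD, n = 3 each), a log2 fold change of 2.40 ± 0.16 (SE) with a limma adjusted p of 0.0110. Mzb1, the other plasma cell gene tested, averaged 0.531 ± 0.425 FPKM in wild type and 1.05 ± 0.125 in knockout and did not pass (limma adjusted p = 0.598). Wdfy1 (ENSMUSG00000073643.11, chromosome 1, 79702262 to 79776143) rose from 4.17 ± 0.210 to 13.9 ± 0.929 FPKM, with a limma adjusted p of 0.0110. Its end overlaps Mrpl44 on the opposite strand, which averaged 22.6 ± 0.452 FPKM in wild type and 22.4 ± 0.162 in knockout. Dbp (ENSMUSG00000059824.12, chromosome 7, 45705088 to 45710203) rose from 8.51 ± 0.507 to 20.4 ± 1.54 FPKM (limma adjusted p = 0.0145), and Sphk2, which overlaps it on the opposite strand, stood at 8.48 ± 0.214 and 8.60 ± 0.0778.

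Most of the genes that fell lie on chromosome 14. Tmem254a, Tmem254b and Tmem254c, which encode transmembrane proteins, fell by 2.01, 2.06 and 2.01 on the log2 scale (limma adjusted p = 0.0110, 0.0110 and 0.0125). They span 25923300 to 26207041 on that chromosome, and Tmem254b and Tmem254c share 100% of their 31-base words with transcripts of other genes, so reads cannot be assigned to 1 copy with certainty. Summed over the 3 copies, the level was 138 ± 24.6 FPKM in wild type and 31.3 ± 3.65 in knockout. Plac9b, between them, fell from 4.59 ± 1.07 to 1.10 ± 0.0408 FPKM (limma adjusted p = 0.0490), and Entpd4, which encodes a nucleotide-hydrolysing enzyme of the secretory pathway, fell from 10.7 ± 0.478 to 5.70 ± 0.162 (limma adjusted p = 0.0409). Plac9b and Entpd4 share 96.6% and 100% of their 31-base words with other genes, so these values too cannot be assigned to 1 copy. Plac9a, Plac9b and Gm9780 summed to 13.7 ± 3.29 FPKM in wild type and 3.03 ± 0.0619 in knockout. Entpd4 and Gm21685 summed to 25.5 ± 1.37 and 13.5 ± 0.496. Entpd4 also overlaps the called predicted model Gm16867 on the opposite strand. Of the 15 called genes, 9 lie on chromosome 14, and 9 share at least 50% of their 31-base words with another gene, as do 473 of all genes tested. Copies of 1 family are not independent calls.

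On other chromosomes, Cdipt (ENSMUSG00000030682.4, chromosome 7, 126975914 to 126980501), which makes phosphatidylinositol, fell from 22.6 ± 0.444 to 9.76 ± 1.08 FPKM (limma adjusted p = 0.0186). Nkiras2, which encodes a small GTPase-like inhibitor of NF-kB signalling, fell from 7.70 ± 1.09 to 2.45 ± 0.467 FPKM (limma adjusted p = 0.0472). Nkiras2 overlaps Dnajc7 and Zfp385c, and Cdipt overlaps Cdiptos, all on the opposite strand. Another 5 called genes were predicted models without a name, all lower in the knockout. Genes outside the threshold that filled the places of the naming rule were Mgll, Slc16a14, Herpud1, Ptgds and H2-DMb1 on the higher side and Plac9a on the lower side, with limma adjusted p between 0.0605 and 0.119. The 15 calls fell to 0 without wild type library 1, without wild type library 3 or without knockout library 2, while 11 genes were called without knockout library 3. Over all genes tested, 16.6% had values that did not overlap between the genotypes, where chance gives 10%.

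**Figure D1:**
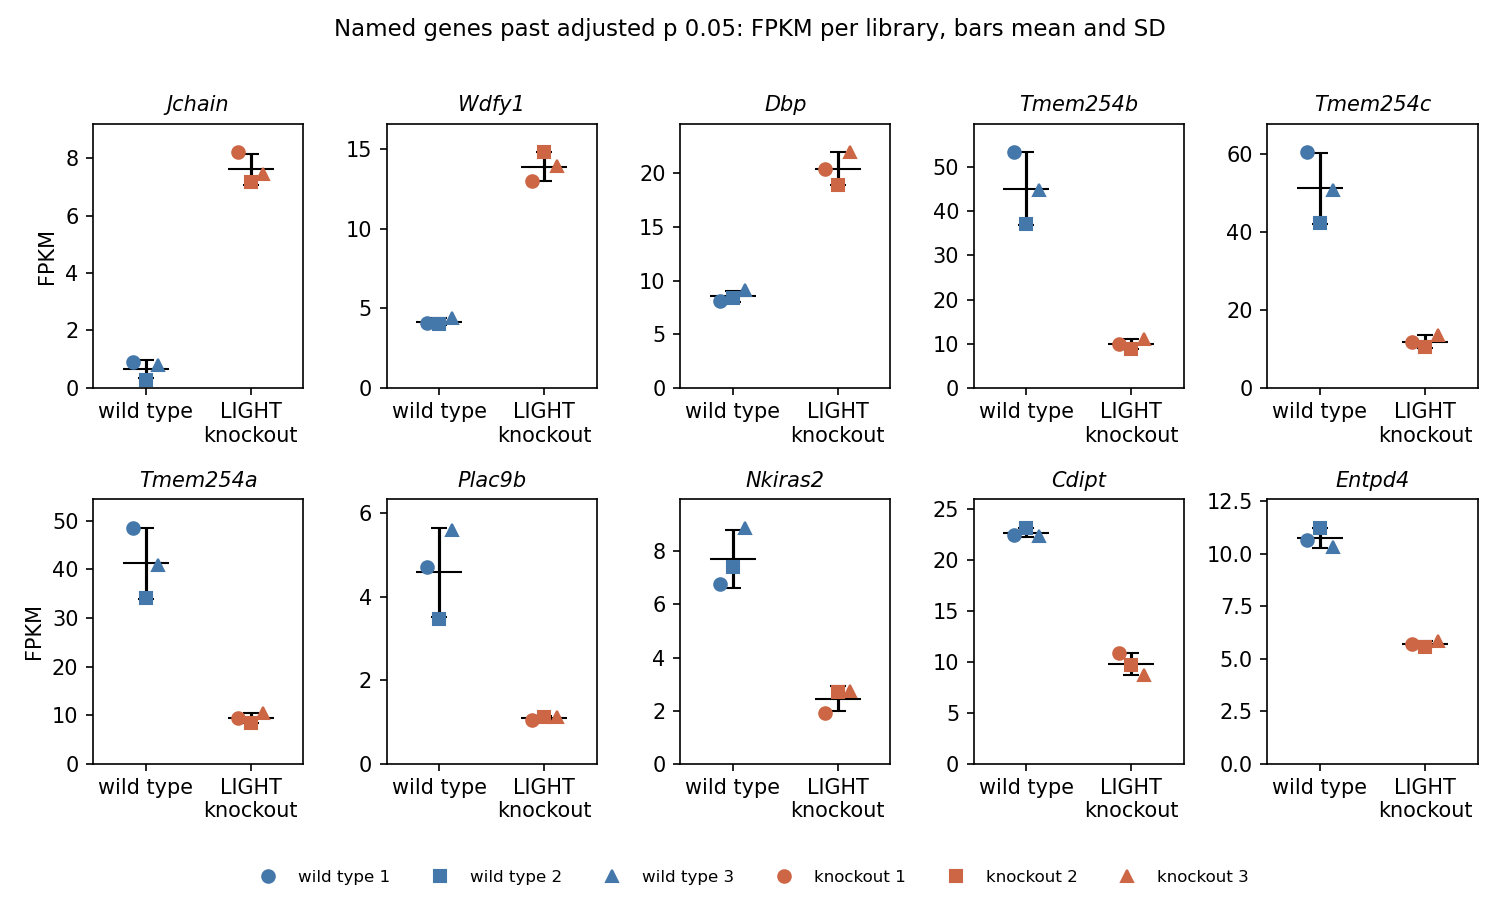
FPKM (vertical axes, from 0) of the 10 named genes past the adjusted threshold in each of the 6 libraries, with points for libraries and bars for the mean and SD of 3. Jchain, Wdfy1 and Dbp lie higher in every knockout library, and Tmem254a, Tmem254b, Tmem254c, Plac9b, Nkiras2, Cdipt and Entpd4 lie lower.

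Genes of proximal tubule function rose as groups in the knockout, and tubular injury genes fell as a group, the latter carried by 1 library. Of 30 proximal tubule transport genes, 27 were higher, with a median log2 fold change of 0.50, and this list rose in camera with the preset correlation (adjusted p = 7.33e-11, but adjusted p = 0.633 with an estimated correlation). Slc7a9, a cystine and neutral amino acid transporter, averaged 17.5 ± 4.01 FPKM in wild type and 31.4 ± 5.86 in knockout (SD, n = 3 each). Slc5a12, a lactate transporter, averaged 19.4 ± 1.45 and 30.9 ± 8.19, and Slc13a3, a dicarboxylate transporter, 68.3 ± 18.9 and 107 ± 5.51. All 9 gluconeogenesis genes were higher, with a median of 0.67 (camera adjusted p = 0.000134, and adjusted p = 0.633 with an estimated correlation), and their median was 0.29 without knockout library 3. In that list Fbp1 averaged 158 ± 28.0 and 239 ± 60.0 FPKM and Pck1, the enzyme that commits carbon to glucose synthesis, 351 ± 150 and 587 ± 64.7. No member of either list passed over all genes or adjusted over the list alone.

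Of 27 tubular injury genes, 22 were lower in the knockout, with a median of -0.58, and the list fell in camera with the preset correlation (adjusted p = 0.00285, but adjusted p = 0.633 with an estimated correlation). Havcr1, which encodes kidney injury molecule 1, stood at 895, 770 and 833 FPKM in the wild type libraries and at 596, 415 and 143 in the knockout libraries. Anxa3, an annexin of injured tubules, stood at 50.4, 52.8 and 53.8 FPKM and at 39.0, 29.5 and 10.6. Neither passed over all genes (limma adjusted p = 0.592 for each) or adjusted over the list alone. Lcn2, which encodes the injury marker lipocalin 2 and was chosen after its values were seen, averaged 183 ± 52.5 and 121 ± 78.2 FPKM, with 30.4 in knockout library 3. Without that library the median of the list was -0.09 and the call ended (camera adjusted p = 0.76).

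The list of the unfolded protein and integrated stress response and the list of clock genes rose in camera with the preset correlation, and each has an adjusted p = 0.633 with an estimated correlation. The median of each list was higher in every knockout library than in any wild type library. Herpud1, which takes part in degradation of misfolded proteins, averaged 38.7 ± 1.38 FPKM in wild type and 87.8 ± 16.6 in knockout (SD, n = 3 each), and the chaperones Pdia4, Creld2 and Sdf2l1 averaged 60.5 ± 2.44 and 87.2 ± 7.22, 27.1 ± 1.75 and 42.3 ± 5.38, and 13.8 ± 3.25 and 26.5 ± 5.94. Of 20 genes of the unfolded protein and integrated stress response, 14 were higher with a median of 0.23, and the list rose in camera (adjusted p = 9.29e-05, and adjusted p = 0.633 with an estimated correlation). None passed over all genes, while 6 higher genes and 1 lower gene passed adjusted over the list alone. The lower gene was Atf5, a transcription factor of the stress response, at 27.1 ± 1.70 and 20.6 ± 2.15 FPKM. Of 14 heat shock genes, 12 were higher with a median of 0.13 (camera adjusted p = 0.00863, and adjusted p = 0.633 with an estimated correlation), among them Dnaja1 at 28.8 ± 2.56 and 41.3 ± 5.76 FPKM and Hsph1 at 17.6 ± 0.250 and 31.6 ± 10.4. The call on the heat shock list ended without wild type library 2 (median 0.07, adjusted p = 0.0789) and without knockout library 1 (median 0.04, adjusted p = 0.276), and the median was 0.19 without wild type library 3. Of the 14 heat shock genes, 3 lie on chromosome 17 within 25 Mb of Tnfsf14. The 11 others had a median of 0.09 (camera adjusted p = 0.0428, and adjusted p = 0.634 with an estimated correlation).

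Of 17 clock genes, 13 were higher, with a median of 0.25, and the list rose in camera (adjusted p = 9.86e-05, and adjusted p = 0.633 with an estimated correlation). Dbp passed over all genes, and Dbp and Per2 passed adjusted over the list alone. Per2, a repressor of the clock, averaged 4.95 ± 1.22 FPKM in wild type and 10.2 ± 1.72 in knockout (SD, n = 3 each). Nr1d1, which represses clock activators, averaged 12.4 ± 1.79 and 16.8 ± 0.658, and Hlf, a transcription factor of the same family as Dbp, 5.09 ± 1.15 and 12.8 ± 6.89. Npas2, a clock activator, averaged 1.38 ± 0.395 and 0.770 ± 0.241 FPKM.

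**Figure D2:**
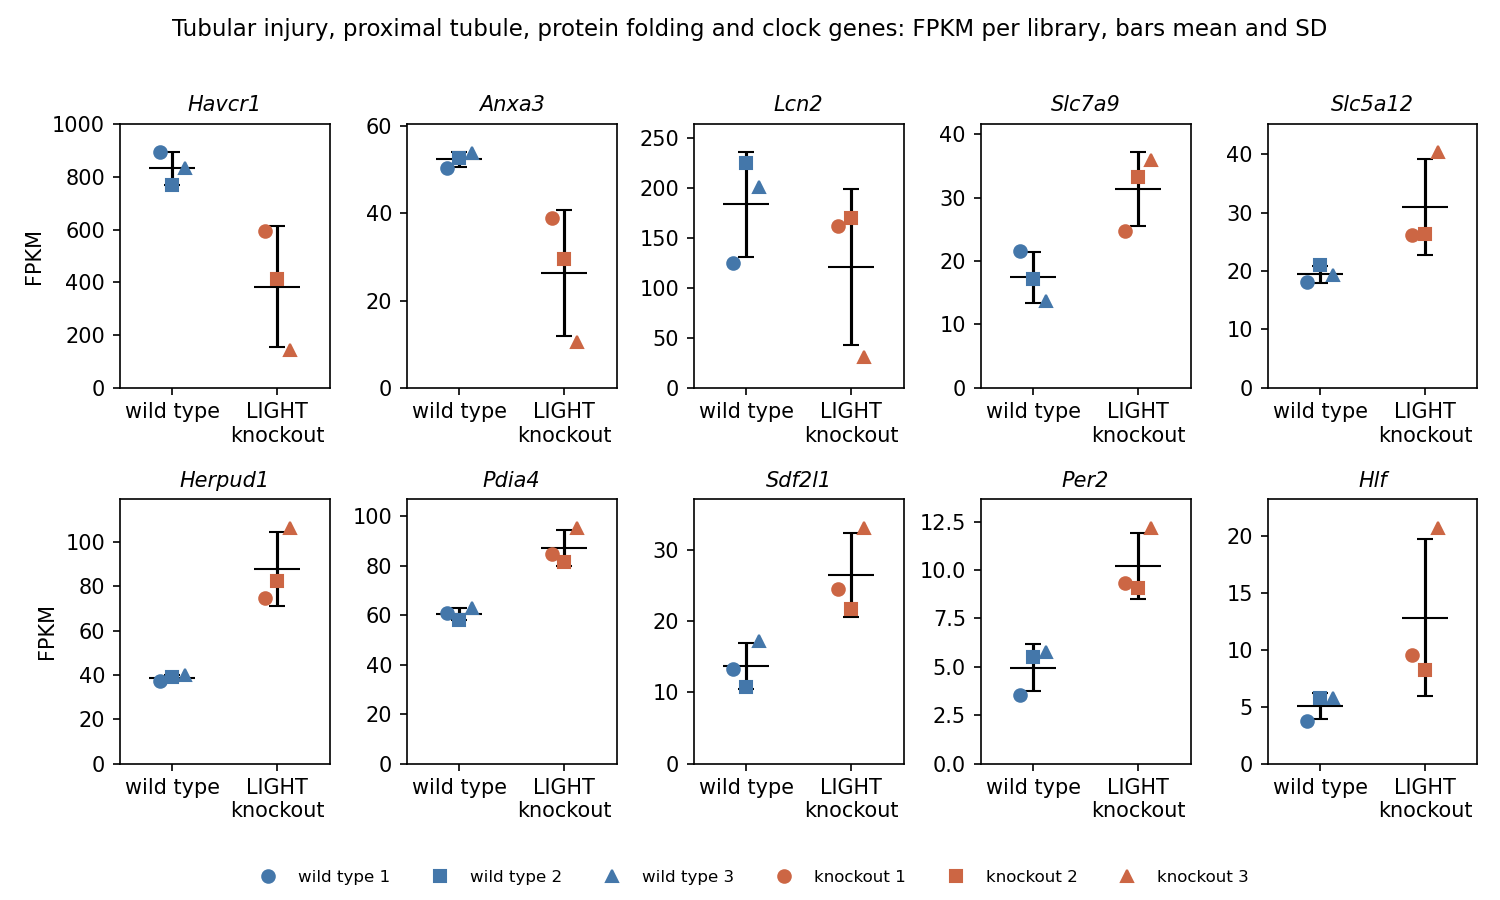
FPKM (vertical axes, from 0) of tubular injury, proximal tubule, protein folding and clock genes in each of the 6 libraries, with points for libraries and bars for the mean and SD of 3. Herpud1 and Per2 lie higher in every knockout library, while Havcr1 is 596, 415 and 143 in the knockout libraries against 770 to 895 in wild type.

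Immune gene groups moved in different directions. All 11 neutrophil genes tested were lower in the knockout, with a median of -0.47, and the list fell in camera (adjusted p = 0.000543, and adjusted p = 0.633 with an estimated correlation). Clec4d, a receptor of myeloid cells, stood at 2.06, 3.67 and 4.41 FPKM in the wild type libraries and at 1.37, 2.04 and 0.546 in the knockout libraries, and S100a9, a calcium-binding protein abundant in neutrophils, averaged 41.1 ± 6.21 and 23.7 ± 10.8 (SD, n = 3 each). The neutrophil median was -0.13 without knockout library 3, -0.29 without wild type library 3 and -0.72 without knockout library 2. Complement and acute phase genes rose, with 13 of 16 higher and a median of 0.41 (camera adjusted p = 0.000193, and adjusted p = 0.598 with an estimated correlation). C4b and C2, components of the classical pathway, averaged 1.75 ± 0.915 and 4.27 ± 1.04 FPKM and 7.89 ± 1.24 and 11.1 ± 0.397, and Cfb, of the alternative pathway, averaged 82.7 ± 8.57 and 107 ± 8.81. C4b, C2 and Cfb lie on chromosome 17 within 25 Mb of Tnfsf14, as do 4 of the 16 list members, and the 12 others had a median of 0.36 (camera adjusted p = 0.0193, and adjusted p = 0.62 with an estimated correlation).

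Interferon-stimulated genes rose with a median of 0.24, and 24 of 27 were higher (camera adjusted p = 0.000125, and adjusted p = 0.633 with an estimated correlation), while without knockout library 3 the median was 0.09. Psmb9, an immunoproteasome subunit, stood at 0.775, 0.445 and 0.399 FPKM in the wild type libraries and at 0.876, 1.04 and 1.27 in the knockout libraries. Gbp3, a guanylate-binding protein, averaged 2.65 ± 0.118 FPKM in wild type and 4.88 ± 2.22 in knockout (SD, n = 3 each). Of the interferon list, 3 members lie on chromosome 17 within 25 Mb of Tnfsf14. The 24 others had a median of 0.24 (camera adjusted p = 0.000308, and adjusted p = 0.634 with an estimated correlation). Of 9 genes of dendritic cells and antigen presentation, 7 were higher (camera adjusted p = 0.0103, and adjusted p = 0.633 with an estimated correlation). H2-DMb1, which helps load peptides on class II molecules, averaged 10.4 ± 0.982 and 17.6 ± 0.493 FPKM and was the 1 member past the threshold adjusted over the list alone, and its partner H2-DMa averaged 3.54 ± 1.16 and 5.96 ± 0.601. H2-DMb1 and H2-DMa are among 5 list members on chromosome 17 within 25 Mb of Tnfsf14, and without these 5 the call ended, with a median of 0.10 over the other 4 genes (camera adjusted p = 0.659). The call also ended without wild type library 2 (adjusted p = 0.0731) and without knockout library 3 (adjusted p = 0.179). Monocyte and macrophage genes did not pass, with 9 of 24 higher and 15 lower (camera adjusted p = 0.176), yet Chil3, a chitinase-like protein of myeloid cells, averaged 14.6 ± 4.73 and 5.38 ± 2.03 FPKM and Itgam, an integrin chain, 4.27 ± 1.61 and 1.96 ± 0.284. Chemokines and cytokines were split, with 12 higher and 11 lower (camera adjusted p = 0.226), and Ccl5, a chemokine for lymphocytes, averaged 1.15 ± 0.417 and 3.00 ± 0.663 FPKM and was the 1 member past the threshold adjusted over the list alone. Cxcl10, an interferon-induced chemokine, averaged 3.54 ± 1.05 and 7.75 ± 1.98 FPKM.

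Genes of mitochondrial metabolism rose by small amounts and genes of ribosomal proteins fell. Of 33 ribosomal protein genes, all 33 were lower, with a median of -0.28 (camera adjusted p = 2.08e-12, and adjusted p = 0.633 with an estimated correlation) and -0.16 without knockout library 3. Rpl30 averaged 69.2 ± 4.12 FPKM in wild type and 55.4 ± 5.57 in knockout, and Rpl11 109 ± 3.76 and 87.0 ± 11.4 (SD, n = 3 each). Of 20 genes of mitochondrial dynamics and mitophagy, 18 were higher, with a median of 0.09 (camera adjusted p = 0.000462, and adjusted p = 0.633 with an estimated correlation). Pink1, a kinase that marks damaged mitochondria, averaged 49.3 ± 4.10 and 64.8 ± 6.78 FPKM, Mtfp1, a protein of mitochondrial fission, 8.15 ± 0.452 and 10.7 ± 1.65, and Sirt3, a mitochondrial deacetylase, 3.95 ± 0.546 and 6.32 ± 1.87. Citric acid cycle genes rose with a median of 0.16 and 15 of 17 higher (camera adjusted p = 0.000659, and adjusted p = 0.633 with an estimated correlation). Among them Sucla2 averaged 31.8 ± 1.56 and 38.8 ± 4.69 FPKM and Idh2 53.4 ± 1.70 and 71.6 ± 16.3, and the median was 0.08 without knockout library 3.

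Nuclear genes of oxidative phosphorylation rose by a median of 0.07, and 36 of 42 were higher (camera adjusted p = 0.00122, and adjusted p = 0.633 with an estimated correlation). Sdha, of complex II, averaged 124 ± 11.1 FPKM in wild type and 156 ± 24.8 in knockout, and Ndufs7, of complex I, 41.9 ± 3.84 and 48.4 ± 1.53 (SD, n = 3 each). The call ended without wild type library 3 (adjusted p = 0.198) and without knockout library 1 (adjusted p = 0.0681), and the median was 0.03 without knockout library 3 and 0.13 without knockout library 2. Of 28 genes of fatty acid oxidation and peroxisomes, 20 were higher, with a median of 0.15 (camera adjusted p = 0.0183, and adjusted p = 0.633 with an estimated correlation). Acadm, a medium-chain dehydrogenase, averaged 77.4 ± 8.32 and 116 ± 27.7 FPKM and Hadh 56.4 ± 6.68 and 71.5 ± 5.43. The median of that list was -0.06 without wild type library 3, and the call also ended without knockout library 1 (adjusted p = 0.294). The 13 mitochondrially encoded genes fell with a median of -0.10 and 12 lower (camera adjusted p = 0.0374, and adjusted p = 0.633 with an estimated correlation), a call that ended without wild type library 1, wild type library 2 or knockout library 2 (adjusted p = 0.181, 0.145 and 0.426).

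Genes of stroma, cell division and cell death fell as lists, each of them dependent on single libraries. Of 26 fibroblast and extracellular matrix genes, 21 were lower, with a median of -0.20 (camera adjusted p = 0.00431, and adjusted p = 0.633 with an estimated correlation). Tagln and Vim, cytoskeletal proteins of contractile and mesenchymal cells, averaged 151 ± 64.2 and 66.9 ± 21.4 FPKM and 35.3 ± 12.5 and 20.7 ± 3.16 (SD, n = 3 each). Of 29 proliferation genes, 25 were lower, with a median of -0.18 (camera adjusted p = 0.00648, and adjusted p = 0.633 with an estimated correlation), and Cdc20, an activator of mitotic exit, averaged 2.18 ± 1.06 and 1.10 ± 0.217 FPKM. Without wild type library 3 both calls ended, with medians of -0.05 and -0.02 (adjusted p = 0.228 and 0.744). The first also ended without knockout library 1 (adjusted p = 0.0634) and the second without knockout library 2 (adjusted p = 0.253). Apoptosis and p53 targets were lower in 19 of 24 (camera adjusted p = 0.0366, and adjusted p = 0.633 with an estimated correlation), with Mdm2 at 12.6 ± 0.818 and 10.4 ± 0.729 FPKM and Bax at 23.4 ± 1.93 and 18.0 ± 3.53. Genes of necroptosis, pyroptosis and ferroptosis were lower in 12 of 17 (camera adjusted p = 0.0446, and adjusted p = 0.633 with an estimated correlation), with the inflammasome adaptor Pycard at 4.98 ± 0.242 and 3.96 ± 0.450 FPKM. The death lists lost their calls without knockout library 3 (adjusted p = 0.326 and 0.179), without wild type library 1 (0.0954 and 0.153) and without knockout library 2 (0.0599 and 0.0679), and the second also without wild type library 3 (0.0553).

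The medians of adipocyte and urothelium markers were highest in knockout library 3. The adipocyte markers Cfd and Adipoq, which encode adipsin and adiponectin, were listed at 63.6 and 13.1 FPKM there and at no more than 0.147 and 0.0659 in any other library. All 11 adipocyte genes were higher on average (camera adjusted p = 0.00384, and adjusted p = 0.633 with an estimated correlation), and the median was -0.02 without that library (adjusted p = 0.808). Of 9 urothelium genes, 8 were higher (camera adjusted p = 0.0446, and adjusted p = 0.633 with an estimated correlation), and Upk3a, a protein of the bladder and pelvic lining, was listed at 9.999 FPKM in knockout library 3 and at 1.22 and 0.826 in the other knockout libraries. The urothelium medians also varied in wild type, at -0.72, 0.38 and 0.43 in wild type libraries 1 to 3. In knockout libraries 1 to 3 they were 0.08, -0.34 and 2.31. Of 15 collecting duct genes, 12 were higher (camera adjusted p = 0.0314, and adjusted p = 0.633 with an estimated correlation), with Slc4a9 at 8.85 ± 1.57 and 11.8 ± 1.57 FPKM. Of 12 male-biased kidney genes, 11 were higher (camera adjusted p = 0.0041, and adjusted p = 0.633 with an estimated correlation), with Acsm3 at 24.9 ± 6.99 and 43.9 ± 14.3 FPKM and Cyp7b1 at 3.62 ± 0.598 and 16.4 ± 13.8. Without knockout library 3 the last 3 calls ended (adjusted p = 0.76, 0.461 and 0.326), and the medians of urothelium and collecting duct genes turned to -0.12 for each. The urothelium and collecting duct calls also ended without wild type library 1 (adjusted p = 0.559 and 0.129), the first without knockout library 1 (0.0634) and the second without wild type library 3 (0.104).

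**Figure D3:**
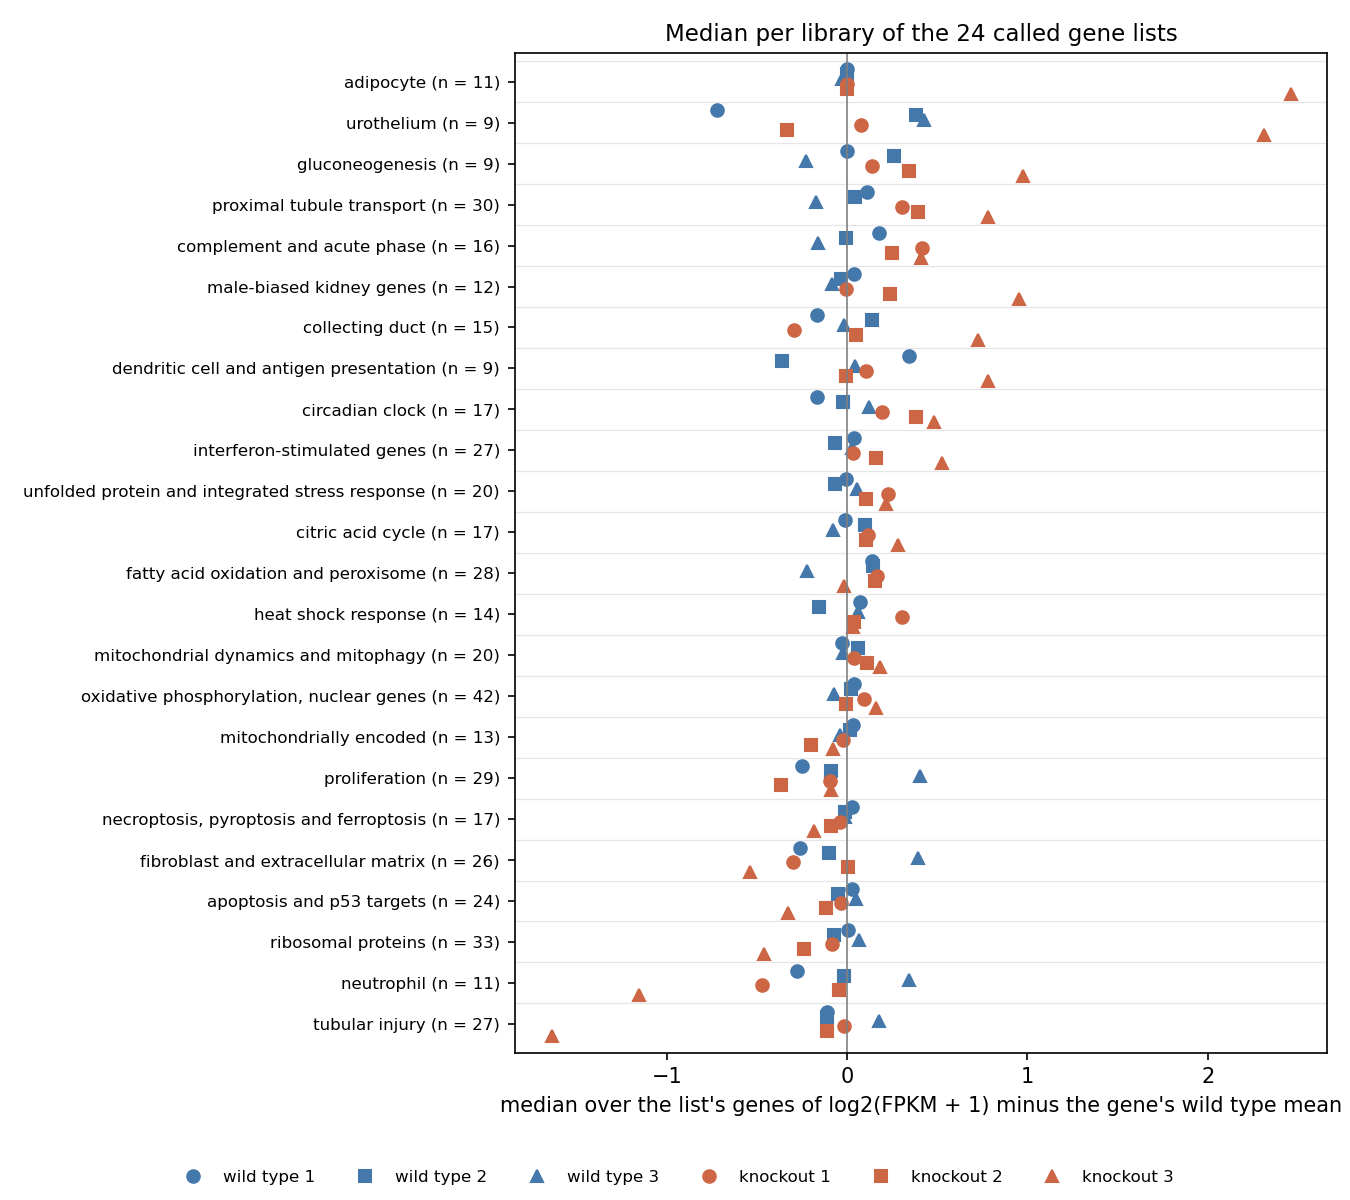
Median log2(FPKM + 1) minus each gene's wild type mean (horizontal axis) for the 24 gene lists called with the preset correlation, 1 point per library and the number of genes tested beside each list. Knockout library 3 lies at -1.64 for tubular injury and at 2.46 for adipocyte genes, while for proximal tubule transport the knockout libraries lie at 0.31, 0.39 and 0.78.

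Other groups gave no call in the unblocked, unweighted comparison of all 12836 genes in FPKM. Podocyte genes were lower in 6 of 10 (camera adjusted p = 0.0596), with Synpo, an actin-binding protein of foot processes, at 4.70 ± 0.251 and 3.15 ± 1.03 FPKM and Cdkn1c at 13.1 ± 0.805 and 11.2 ± 0.172 (SD, n = 3 each). Antioxidant genes were lower in 13 of 20 (camera adjusted p = 0.176), and Gsta1, a glutathione transferase, averaged 87.1 ± 20.5 and 32.2 ± 21.4 FPKM, while G6pdx averaged 31.2 ± 2.62 and 22.2 ± 4.70. Immediate early genes were lower in 14 of 18 (camera adjusted p = 0.0855), with Nr4a1 at 4.57 ± 0.885 and 2.74 ± 0.623 FPKM, and it was called only with 1 knockout library left out, in different directions. Without knockout library 1 or 2 the list was called lower, with medians of -0.40 and -0.43 (adjusted p = 0.00299 and 0.00829). Without knockout library 3 it was called higher, with a median of 0.27 (camera adjusted p = 0.000178, but adjusted p = 0.758 with an estimated correlation). Genes controlled by NF-kB, a pathway downstream of LIGHT receptors, had 8 of 17 higher and a median of -0.06 (camera adjusted p = 0.853). Their median was 0.11 without knockout library 3 (camera adjusted p = 0.0261, but adjusted p = 0.758 with an estimated correlation). Monocyte and macrophage genes, chemokines and podocyte genes were also called without that library, with medians of -0.21, 0.14 and -0.16 (camera adjusted p = 0.00672, 0.00386 and 0.00904). With an estimated correlation each of them had an adjusted p of 0.758 there. Glycolysis and hypoxia genes were lower in 14 of 22 (camera adjusted p = 0.441), with Aldoa at 159 ± 5.31 and 135 ± 4.75 FPKM. Endothelial genes, endothelial activation, erythrocyte genes, genes of the loop of Henle and distal nephron, and LIGHT receptors with related ligands had camera adjusted p of 0.828, 0.828, 0.0855, 0.0736 and 0.247. Loop of Henle and distal nephron genes were called higher without wild type library 2, knockout library 1 or knockout library 2 (adjusted p = 0.0373, 0.0133 and 0.00574), while without knockout library 3 their median turned to -0.21 (adjusted p = 0.179). Erythrocyte genes were called higher without knockout library 2 (adjusted p = 0.000562). Antioxidant genes were called lower without wild type library 3 (adjusted p = 0.0127) and knockout library 1 (0.00506), podocyte genes without wild type library 3 (0.0149), and monocyte and macrophage genes without wild type library 2 (0.0352), while chemokines were called higher without wild type library 3 (0.0437).

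In total, camera with the preset correlation of 0.01 called 24 of 36 lists, and with an estimated correlation it called 0, with adjusted p between 0.598 and 0.946 and 1 list at an unadjusted p under 0.05. The rotation test fry called 0, with 3 lists at an unadjusted p under 0.05 and a lowest adjusted p of 0.228. Of the 24 lists, 10 were called whichever of the 6 libraries was left out. Other splits of the 6 libraries into 3 and 3 gave 12 to 24 lists in camera with the preset correlation. Many lists were therefore called whatever the grouping.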

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

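The alternatives without knockout library 3 for the estimated correlation, without near-identical copies and without genes near Tnfsf14 were added after the data were seen. The count of 15 genes was 9 with a mean of at least 5 FPKM, 52 with library weights (29 higher, 23 lower), 5 without near-identical copies and 0 with the replicate number as a block, where 884 genes had an unadjusted p under 0.05. Leaving out near-identical copies removed 9 of the 15 called genes themselves, and the 5 still called were all among the 15. For the other settings the cause was not tested. Leaving out 1 library gave 0 to 11 genes: 0 without wild type library 1, wild type library 3 or knockout library 2 (883, 563 and 875 at an unadjusted p under 0.05), 6 without wild type library 2, 7 without knockout library 1 and 11 without knockout library 3, of which 10 were among the 15. Fewer libraries also leave fewer degrees of freedom. The other scalings, pseudocounts and variance models gave 12 to 16 genes, and no scaling moved the median of all genes by over 0.1 on the log2 scale. Same-numbered libraries did not deviate together (r = 0.146, -0.133 and -0.0193), too few values to exclude pairing.

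The 24 lists were 0 with an estimated correlation, 0 with fry, 0 with an estimated correlation and without knockout library 3, 14 with library weights, 25 with the replicate block and 25 with camera on ranks, which keeps the preset correlation. They were 19 to 23 with each library left out, though not always the same lists: 16 of the 21 without knockout library 3 and 9 of the 14 with library weights were among the 24 in the same direction. Without genes near Tnfsf14 there were 24, of which 23 were the same, with podocyte genes gained (adjusted p = 0.0394) and antigen presentation lost (adjusted p = 0.659), and camera turned for NF-kB targets (median -0.023, adjusted p = 0.976). The estimated correlation ranged from -0.028 for glycolysis and hypoxia to 0.913 among ribosomal proteins, against the preset 0.01. For necroptosis genes it was 0.0090, yet the unadjusted camera p rose from 0.0297 to 0.0937. For complement genes it was 0.016, and that p rose from 3.75e-05 to 0.0166. A higher correlation therefore does not account for every call lost. For the estimated correlation, fry and library weights the cause was not tested.

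The cause was not tested where the direction of a value or of camera turned. With library weights the values were -0.34 for Egf and, as list medians, -0.13 for loop of Henle, 0.013 for collecting duct (only the direction of camera turned), 0.040 for endothelium, 0.34 for endothelial activation, -0.013 for oxidative phosphorylation, 0.19 for NF-kB targets, 0.22 for immediate early genes, -0.071 for erythrocyte and -0.25 for urothelium genes. With the replicate block, camera turned for endothelium (median -0.0071) and endothelial activation (-0.042). NF-kB targets had 0.013 without a filter and 0.028 with a mean of at least 5 FPKM, and mitochondrially encoded genes 0 with quantile normalization. With each library left out, the ranges were -0.22 to 0.039 for Ltbr, -0.44 to 1.76 for Egf, -0.17 to 0.20 for chemokines, -0.12 to 0.42 for collecting duct, -0.23 to 0.021 for endothelial activation, -0.091 to 0.071 for endothelium, -0.062 to 0.22 for fatty acid oxidation, -0.43 to 0.27 for immediate early genes, -0.21 to 0.45 for loop of Henle and -0.17 to 0.11 for NF-kB targets. Further medians that kept their sign but moved by over 1.5 times ranged from -0.90 to -0.091 for tubular injury, 0.032 to 0.13 for oxidative phosphorylation, 0.043 to 0.19 for heat shock, -0.31 to -0.025 for proliferation, -0.33 to -0.049 for fibroblast, -0.23 to -0.082 for apoptosis, -0.25 to -0.088 for necroptosis, -0.14 to -0.064 for mitochondrially encoded and 0.055 to 0.43 for male-biased genes. Those that changed sign ranged from -0.012 to 0.48 for antigen presentation, -0.020 to 1.22 for adipocyte, -0.12 to 1.26 for urothelium, -0.21 to 0.10 for monocyte and macrophage and -0.0031 to 0.32 for erythrocyte genes. Of 1717 values of 97 named genes, 1597 kept their direction and side of the threshold. Only 15 of the 97 were called in the main comparison, and the others could keep their side only by staying uncalled. In 99 values a called gene lost its call, in 18 an uncalled gene gained one and in 3 the direction turned. The level of Tnfsf14 was not run. Depth is unknown and its effect on error was not measured.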

Other observations

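The tests of near-identical copies, of mouse line, of genes near Tnfsf14, of another tissue and of other splits of the called genes were chosen after their results had been seen. Apart from the comparisons above, a few abundant genes were out of line in 1 library while the other 5 stayed together. Of 5064 genes with a mean of at least 10 FPKM, 27 were so in knockout library 3. Egf, made in the distal nephron, was listed at 55.0 FPKM there and had a median of 1.88 in the others. Krt20, a keratin of injured tubules, was at 8.07 against a median of 86.9. In knockout library 2, mt-Atp6 was at 615 FPKM against a median of 3630, and Tmem127 at 2.45 against 28.8.

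The first pattern is the set of 15 called genes, which only 1 of the 10 splits of 6 libraries into 3 and 3, the real one, gave, with 1 gene as the highest of the others, although with 10 splits the share cannot fall under 0.05. The sums over 3 families of near-identical copies were 4.40, 4.52 and 1.88 times as high in wild type, with no overlap. Each copy summed was itself lower in the knockout, so reads did not only move among these copies. The sums could not show reads moving to genes outside them, and that was not tested. Of the called genes, 0 lie within 25 Mb of Tnfsf14. Only 354 of the 12836 genes tested lie there, so few calls were to be expected there in any case. Their position argues only against a direct effect of DNA of another strain within that region. An effect of such DNA on the called genes from a distance was not tested. A substrain difference elsewhere in the genome may account for them and cannot be told apart from the knockout, because the labels used here do not say whether the genotypes were littermates or separate lines: Nnt, which lacks exons in C57BL/6J, was 2.17 times as high in the knockout (8.27 ± 0.732 and 17.9 ± 3.72 FPKM, SD, n = 3 each, higher in 3 of 3 libraries, limma adjusted p = 0.242). Within 25 Mb of Tnfsf14, 4.24% of 354 genes had an unadjusted p under 0.01, against 1.51% elsewhere (odds ratio 2.88, Fisher exact p = 0.0005366, two-sided, with neighbours counted as independent), among them H2-DMb1, C4b, C2, H2-Q6, H2-T24, Sult1c2, Gtf2h4 and Apobec2. Of 258 overlapping windows apart from that region, 6 on 4 chromosomes had as high a share. Those on chromosomes 1, 7 and 14 hold called genes (Wdfy1, Dbp and the Tmem254 copies), so they are not a background free of the called genes. The windows therefore do not settle the question. Flanking DNA stays open for the genes near Tnfsf14, the antigen presentation and complement genes included.

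The second pattern is knockout library 3. All 11 genes called without it lay on the knockout side of the midpoint in it, 100%, which argues against a wild type kidney under a knockout label. Its proximal tubule transport median was 0.67 (log2) above the median of the other 5 libraries while its tubular injury median was the lowest, which argues against dilution by another tissue as the whole cause, although adipocyte markers were present in it. A milder injury in this animal is a candidate explanation: the injury median was -1.64 in it, while the other 2 knockout libraries differed from wild type by -0.0502, within the wild type range of 0.288. The counts of lists do not separate this from the genotype, since 2 of the 10 splits gave 24 lists, the real one and 1 other. The splits other than the real one gave 12 to 24 lists, and with 10 splits the share cannot fall under 0.05.

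The third pattern is the clock genes. Genes that peak with Dbp, such as Per3, had a median log2 fold change of 0.51, and genes of the opposite phase, such as Arntl, a median of -0.02, a difference of 0.53 that is just over the 0.5 set beforehand. Kidneys collected at another time of day could give this, and a knockout effect on the clock stays open, untested, since the labels used here give no time of collection. Without knockout library 3 the difference was 0.51, 95.9% of its value, which argues against that library as the cause.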
